A study of Mus musculus with 8 samples.

How the data were processed

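RNA was measured in the tibialis anterior, a muscle of the lower leg, of male C57BL/6 mice aged 8 weeks. Per the series design, the left muscle received 25 µg of the empty plasmid pcDNA3 and the right muscle 25 µg of a plasmid that expresses FLAG-tagged ATF4, a transcription factor of the stress response, by electroporation in vivo. RNA was taken 11 days later from fed mice, per the labels' protocols, and the experiment was carried out 4 times, which gave 8 arrays, 4 per group. The RNA was amplified by single-primer isothermal amplification, labelled with biotin and hybridised to mouse exon arrays, per the labels' protocols.

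The deposited values are on a log2 scale and were made by the authors with RMA (background correction, normalization between arrays and summary of the probes of a probe set), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. The notes also name the genome build hg18, a human build, and what it was used for on these mouse arrays is not given in the sources used here, so no genome coordinates are reported. The log2 scale was read from the values, whose medians lay between 4.29 and 4.44 per array. The table holds 16755 probe sets with 1 value each per array. The platform annotation lists 1 gene for 14996 of them, several genes for 1019 and none for 740. Entrez identifiers of 14941 probe sets matched the GRCm38.p6 gene table, and 0 symbols had to be updated. Genes are named only from probe sets with 1 gene. Where a gene had several probe sets, the one with the highest mean over the 8 arrays stood for it, which left 14860 genes. Scanner signals and detection calls were not used here, so background cannot be separated from low expression. The number of arrays limits the precision.

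The comparison was fitted with limma 3.58.1 in R 4.3.3, on all 16755 probe sets, as ATF4 minus empty vector with the experiment number as a fixed block. The moderated variances used a prior that follows the mean level (trend), with 4.96 prior and 3 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. A second count required a 1.5-fold difference as well. The pairing comes from the series design, in which the left and right muscles of the same mice were set against each other in each experiment. The correlation of the paired arrays' deviations from their group means was 0.07, 0.31, 0.55 and 0.05 in experiments 1 to 4, and 5 of the 8 arrays correlated best with their partner. The values alone would therefore not have established the pairs of experiments 1 and 4. The labels do not say whether an experiment was 1 mouse or a pool. The p-values of probe sets therefore measure the spread of the differences over experiments, whatever that contains, moderated by the prior.

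Gene lists were fixed before the data were examined. The 33 lists cover amino acid synthesis and transport, stress responses, atrophy, growth arrest, denervation, fibre type, metabolism, protein turnover, interferon response, proliferation and the other cell types of a muscle, and they have 509 members, of which 407 were measured and 102 were not matched to a probe set with 1 gene. For each list, members past the threshold were counted over all probe sets and adjusted over the list alone. The list as a whole was tested with camera in limma, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg over the 33 lists. This test compares the members with all other genes, so its p-value does not measure the spread between experiments. Camera with an estimated correlation and fry were the alternatives. An exact permutation test of the list means per array, over all 35 splits of the 8 arrays, was added after the data were examined.

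The genes named were chosen by a rule fixed before the data were examined. They are Atf4, up to 12 passing genes per direction, the 6 genes of smallest p per direction where fewer than 4 passed, and up to 4 members of smallest p of each list described. Myl2, Tpm3 and Mybpc1 were singled out after their values had been seen, and so were the 8 genes plotted by experiment, which are a subset of the named genes. Probe sets 6784526 and 6969997 are annotated to several genes and are given by identifier, a choice also made after their values were seen.

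Other settings tried were no block, a random block (duplicateCorrelation, with statmod 1.5.0), variance priors without trend or robust, median centring, quantile normalization, leaving out the dimmest 25% or 50% of probe sets, array weights, other thresholds, a test against a 1.2-fold limit, the mean of a gene's probe sets, and leaving out each experiment or each array in turn. The fit was tested on simulated data with the fitted variances, 4 pairs, 16755 probe sets and 200 changed ones, in 20 simulations. It recovered 12% of 1.5-fold changes, 75.1% of 2-fold, 94.8% of 3-fold and 98.4% of 4-fold changes, and 4.43% of the calls were false. The simulated variances were at first drawn from the moderated estimates, which gave more false calls than the threshold allows, and were then drawn from the fitted prior. Simulated errors were independent and followed the fit's own model, so the share of false calls in the real arrays was not measured. With no change simulated and no correlation between genes, camera called 0 lists in the 20 simulations, and it found the denervation list in 20 of 20 when its members were shifted by 0.3. Members of a list were not correlated there, so false list calls in the real arrays were not measured either. Plots were drawn with matplotlib 3.10.9.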

Results

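The data are 8 exon arrays from the tibialis anterior of mice, 4 from muscles transfected with empty plasmid and 4 from muscles transfected with a plasmid for ATF4, a transcription factor that turns on genes of amino acid supply during stress. Each of the 4 experiments gave 1 array of either kind, from the left and the right leg. The 16755 probe sets correlated between arrays with r from 0.916 to 0.981, across probe sets, which are not independent replicates. The comparison addresses which muscle mRNAs differ when ATF4 is overexpressed. All differences below are ATF4 minus empty vector on the log2 scale, with n = 4 pairs, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

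The transfected gene itself was not measurably higher. Atf4 (probe set 6831994) stood at 6.34 ± 0.12 (SD, n = 4) with empty vector and 6.53 ± 0.24 (SD, n = 4) with ATF4 plasmid, a difference of 0.18 (SE 0.11, adjusted p = 0.846). It was 0.24, 0.31, 0.24 and -0.05 in experiments 1 to 4. The 95% interval of the difference ran from -0.08 to 0.45, so a rise of more than 1.36-fold at this probe set lies outside it. Which part of the Atf4 transcript the probes cover is not given in the sources used here, and probes outside the coding sequence on the plasmid would not detect it. The right muscles are therefore called ATF4-labelled.

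Transcripts of H19 and Tnni1 rose in the ATF4-labelled muscles. H19, an imprinted long noncoding RNA abundant in fetal muscle, rose 2.33-fold, from 7.43 ± 0.34 to 8.65 ± 0.36 (SD, n = 4; difference 1.22, SE 0.10, adjusted p = 0.025). Tnni1, the slow skeletal muscle isoform of troponin I, rose 2.40-fold, from 4.29 ± 0.16 to 5.55 ± 0.23 (SD, n = 4; difference 1.26, SE 0.11, adjusted p = 0.025). Both were higher in 4 of 4 pairs. A probe set annotated to 3 genes, 6784526, rose by 2.01 (SE 0.18, adjusted p = 0.025). These 3 probe sets, 2 of them single genes, were all that passed the threshold, each by more than 1.5-fold, and 0 probe sets fell. At an unadjusted p under 0.05 there were 1006 probe sets, 542 higher and 464 lower, where chance gives 838. This count was 609 without the pairing, and 1124, 871, 768 and 1011 without experiments 1 to 4 in turn. Probe sets are not independent, so 838 is no firm bound. Without each experiment in turn the differences stayed between 1.18 and 1.25 for H19 and between 1.24 and 1.33 for Tnni1, and neither passed. Without experiment 1, 2, 3 or 4 in turn, the adjusted p was 0.111, 0.118, 0.211 and 0.0669 for H19 and 0.147, 0.0831, 0.292 and 0.216 for Tnni1. Without the pairing in the fit, H19 had an adjusted p of 0.163 and Tnnt2 passed in its place (adjusted p = 0.0335). With median centring the differences were 1.18 and 1.23 and neither gene passed (adjusted p = 0.0854 for both).

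The next genes by p-value were higher in 4 of 4 pairs without passing the threshold. Tnnt2, the cardiac troponin T that embryonic skeletal muscle also expresses, differed by 1.42 (SE 0.16). Uchl1, a ubiquitin hydrolase, differed by 1.34 (SE 0.16), Ankrd1, a titin-binding ankyrin repeat protein, by 1.204 (SE 0.14), and Asns, asparagine synthetase, by 1.19 (SE 0.14). The adjusted p was 0.0742 for these 4 genes. All 4 passed with a random block for the pairs (adjusted p from 0.00802 to 0.0289), without the dimmest 25% of probe sets (0.0329 to 0.045) or 50% (0.0174 to 0.029) and with array weights (0.0101 to 0.016). The array weights were equal within each pair, at 0.90, 0.94, 2.71 and 0.44 in experiments 1 to 4. They therefore weighted experiments, not single arrays, and most of all experiment 3. Map1b, a microtubule-associated protein, differed by 0.89 (SE 0.12), and Sln, sarcolipin, an inhibitor of the sarcoplasmic calcium pump, by 1.37 (SE 0.18), both at an adjusted p of 0.130. Both passed without the dimmest 50% and with array weights, and Map1b also with the random block. In the other direction, 6 genes were lower in 4 of 4 pairs and did not pass. The olfactory receptor genes Olfr32, Olfr558 and Olfr978 differed by -1.27 (SE 0.19), -0.72 (SE 0.14) and -0.94 (SE 0.18), Nkrf by -0.61 (SE 0.11), Gzmb, granzyme B, by -0.60 (SE 0.11), and Dstn, the actin-depolymerising protein destrin, by -0.59 (SE 0.11). Their adjusted p ran from 0.160 for Olfr32 to 0.431 for Olfr978, and Olfr32 passed with array weights (-1.46, adjusted p = 0.0192). The level of Olfr32 was at the 4.45 percentile of all probe sets, where background weighs most.

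**Figure D1:**
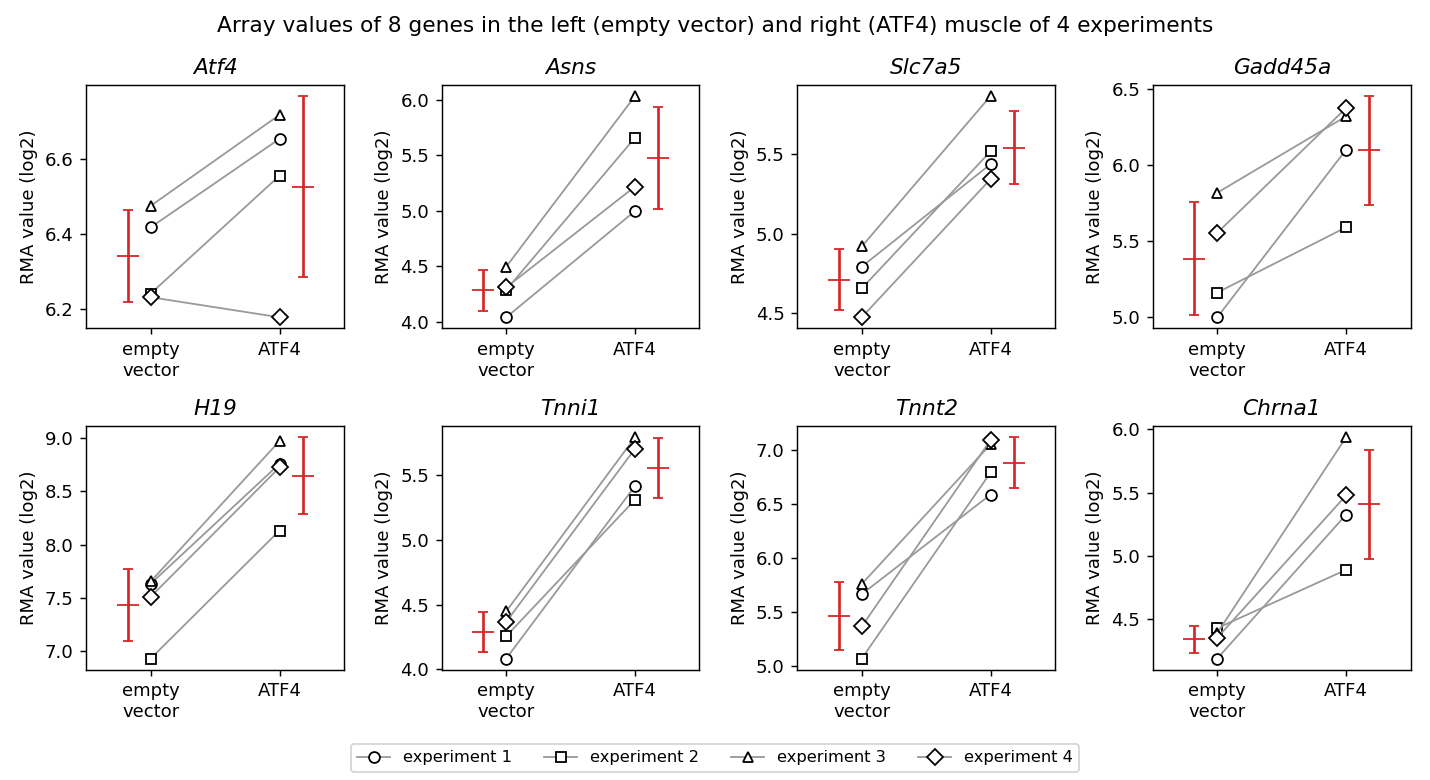
Log2 RMA values (vertical axes, which do not start at 0) of 8 genes in the empty vector and ATF4 muscles; each symbol is 1 array, grey lines join the muscles of 1 experiment, and red bars give the mean ± SD of 4 arrays. H19, Tnni1, Tnnt2, Asns, Slc7a5, Gadd45a and Chrna1 are higher in 4 of 4 experiments and Atf4 in 3 of 4, and of these genes H19 and Tnni1 passed the threshold over all probe sets.

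Genes of amino acid synthesis were higher as a group. Of 11 measured members 9 were higher, with a median of 0.22, and the list was shifted (camera adjusted p = 0.000763; adjusted p = 0.407 with an estimated correlation). No member passed over all probe sets, and 3 passed adjusted over the list alone: Asns, Psat1 of serine synthesis (0.64, SE 0.14) and Mthfd2 of mitochondrial folate metabolism (0.44, SE 0.12). Aldh1l2, another mitochondrial folate enzyme, differed by 0.34 (SE 0.11). Amino acid transporters shifted the same way, with 9 of 13 members higher and a median of 0.17 (camera adjusted p = 0.0119; adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, 3 transporters were higher, Slc7a5 by 0.83 (SE 0.11), Slc7a3 by 0.60 (SE 0.12) and Slc7a11, the cystine carrier, by 0.48 (SE 0.13), and Slc43a1 was lower, by -0.41 (SE 0.13). The transporter call was lost without experiment 3 (adjusted p = 0.147).

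Other stress lists were not shifted. Cytosolic tRNA synthetases were split, 8 of 16 higher, with a median of 0.01 that turned negative with median centring (camera adjusted p = 0.860). Gars differed by 0.41 (SE 0.13) and Wars by -0.58 (SE 0.17). This list was called higher when experiment 4 was left out (adjusted p = 0.00489). Of 18 stress response factors 12 were higher, with a median of 0.08 (camera adjusted p = 0.199; called with quantile normalization, adjusted p = 0.0343). Ppp1r15a, a regulatory subunit of the eIF2α phosphatase, differed by 0.31 (SE 0.13), Fgf21 by 0.29 (SE 0.13), Sesn2 by 0.29 (SE 0.14) and Vldlr by -0.37 (SE 0.17). Fgf21 differed by 0.19 without experiment 3, Sesn2 by 0.19 without experiment 2, and Vldlr by -0.57 without experiment 1 and -0.23 without experiment 4. Chaperones and degradation factors of the endoplasmic reticulum had 10 of 15 members lower and a median of -0.01 (camera adjusted p = 0.229), with Pdia6 at -0.34 (SE 0.11). Antioxidant genes had 5 of 9 lower and a median of -0.09 (camera adjusted p = 0.204), with Nqo1 at -0.31 (SE 0.11) and Prdx1 at -0.54 (SE 0.20), or -0.30 without experiment 4.

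The list of genes linked to denervation had the smallest camera p. All 13 measured members were higher, with a median of 0.34 (camera adjusted p = 1.51e-06; adjusted p = 0.407 with an estimated correlation). Of these, Cdh15, Hdac9, Hdac4, Ky and Dach2 differed by only 0.006 to 0.09. Over all probe sets 0 members passed, and 7 passed adjusted over the list alone. They included Chrna1 and Chrnd, subunits of the muscle acetylcholine receptor, at 1.07 (SE 0.17) and 0.43 (SE 0.12), the adhesion molecule Ncam1 at 0.64 (SE 0.15) and Musk, the receptor kinase of the neuromuscular junction, at 0.39 (SE 0.12). The list mean per array was 4.67 to 4.74 with empty vector and 4.94 to 5.13 with ATF4. An exact permutation test gave p = 0.0286, two-sided, the smallest that 8 arrays allow, and 0.236 after adjustment over the 33 lists. Exchanges within pairs gave an exact p of 0.125, the smallest that 4 pairs allow. Of the other lists called by camera, the first test gave an exact p of 0.0286 for amino acid synthesis, 0.0857 for amino acid transport, 0.114 for slow fibre genes and for adipocyte genes, and 0.257 to 0.629 for the remaining 4. That test ignores the pairing. Exchanges within pairs gave an exact p of 0.125 for amino acid synthesis, amino acid transport and slow fibre genes too, and 0.25 to 0.5 for the other called lists. Markers of Schwann cells and nerve were not shifted (4 of 7 higher, median 0.07, camera adjusted p = 0.576). Their median was -0.06 without experiment 4. S100b differed by 0.46 (SE 0.13).

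Slow fibre genes were shifted up, with 6 of 9 members higher and a median of 0.31 (camera adjusted p = 0.000370; adjusted p = 0.407 with an estimated correlation). Of these, 1 rose over all probe sets (Tnni1), and 4 passed adjusted over the list alone: Tnni1, Tnnc1, the slow and cardiac troponin C, at 1.10 (SE 0.15), the muscle LIM protein gene Csrp3 at 0.81 (SE 0.12) and the cardiac calsequestrin gene Casq2 at 0.71 (SE 0.18). Myl2, the slow regulatory myosin light chain, was lower in 4 of 4 pairs, at -0.86 (SE 0.34, adjusted p = 0.796). It differed by -0.02, -0.67, -0.37 and -2.39 in experiments 1 to 4 and by -0.35 without experiment 4. The other lower members were Tpm3 at -0.16 (SE 0.11) and Mybpc1 at -0.06 (SE 0.10), so the list did not rise as a whole. Fast fibre genes were not shifted (10 of 13 lower, median -0.03, camera adjusted p = 0.343), nor were excitation-contraction genes (10 of 15 lower, median -0.05, camera adjusted p = 0.619). Both medians turned positive with quantile normalization. Several myosin heavy chain genes, among them Myh7, Myh2, Myh1 and Myh4, had no probe set with 1 gene. Myogenic regulators had 11 of 13 members higher and a median of 0.14 without passing (camera adjusted p = 0.0686). They passed without the pairing (adjusted p = 0.0343), with quantile normalization (0.00827) and without the dimmest 25% of probe sets (0.0426). Their median was 0.05 without experiment 1 (camera adjusted p = 0.1425) and 0.07 without experiment 3 (0.173). Igf2, a fetal growth factor, passed adjusted over the list alone at 0.96 (SE 0.14).

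Atrophy genes were not shifted, with 13 of 18 lower and a median of -0.07 that was close to 0 with quantile normalization (camera adjusted p = 0.204). Trim63 and Eif4ebp1, also on this list, were not matched to a probe set with 1 gene. Fbxo32, the muscle ubiquitin ligase atrogin-1, was lower in 4 of 4 pairs at -0.38 (SE 0.15), or -0.22 without experiment 4, and did not pass. Growth arrest genes were not shifted as a list (8 of 13 higher, median 0.01, camera adjusted p = 0.205), and the median turned negative with median centring. Without experiment 4 the list was called higher (adjusted p = 0.0394). Adjusted over the list alone, 2 members were higher, Gadd45a at 0.71 (SE 0.14) and Cdkn1a, the cell cycle inhibitor p21, at 0.55 (SE 0.11), both in 4 of 4 pairs. Proliferation genes had 9 of 15 members higher and a median of 0.06, or -0.04 without experiment 4 (camera adjusted p = 0.860 with all experiments).

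Genes of the citric acid cycle and fatty acid oxidation were called lower as a list in the main fit. Of 14 members 10 were lower, with a median of -0.10 (camera adjusted p = 0.0352, and 0.578 with an estimated correlation). No member passed by either adjustment. Acadm and Hadha, enzymes of fatty acid oxidation, differed by -0.35 (SE 0.14) and -0.26 (SE 0.11), and Acadm by -0.22 without experiment 4. The call was lost without experiment 3 (adjusted p = 0.154) or 4 (0.379), without the pairing (0.0536), without the dimmest 25% of probe sets (0.0734), with median centring (0.0634) and with quantile normalization (0.840). The list mean differed by -0.04, 0.01, -0.11 and -0.25 in experiments 1 to 4. In experiment 4 the ATF4 array had a narrower spread of values (SD 1.14) than its partner (SD 1.31). With quantile normalization the median was -0.004, so a compressed signal range is not excluded for this list.

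Camera also called 3 lists of markers of other cells, none of which kept the same direction in all experiments. Macrophage markers were shifted up, with 12 of 15 higher and a median of 0.18 (camera adjusted p = 0.0229; adjusted p = 0.660 with an estimated correlation), among them C1qb at 0.55 (SE 0.14) and Laptm5 at 0.32 (SE 0.13). The macrophage list mean differed by 0.32, 0.39, 0.06 and -0.08 in experiments 1 to 4. The call was lost without experiment 1 (adjusted p = 0.212) or 2 (0.305) and without the pairing (0.162). Fibroblast and matrix genes were shifted up, with 11 of 15 higher and a median of 0.15 (camera adjusted p = 0.0352; adjusted p = 0.691 with an estimated correlation). Fn1, fibronectin, differed by 0.46 (SE 0.13), Col6a3 by 0.42 (SE 0.15), or 0.26 without experiment 4, and Bgn by 0.37 (SE 0.14). The mean of the fibroblast and matrix list differed by 0.19, -0.07, -0.02 and 0.53 in experiments 1 to 4, higher in 2 of 4. The list was lost without experiment 1 (adjusted p = 0.194) or 4 (0.621). Adipocyte genes were shifted down, with 8 of 11 lower and a median of -0.17 (camera adjusted p = 0.0307; adjusted p = 0.578 with an estimated correlation). Adipoq, adiponectin, differed by -0.46 (SE 0.16), Lpl by -0.43 (SE 0.16), Cd36 by -0.39 (SE 0.14) and Car3 by -0.37 (SE 0.12). Without experiment 4 Adipoq differed by -0.27 and Cd36 by -0.22, and without experiment 1 Lpl differed by -0.26. Muscle fibres express Lpl, Cd36 and Car3 too. The adipocyte list mean differed by -0.14, 0.10, -0.30 and -0.24 in experiments 1 to 4. The list was lost without experiment 3 (adjusted p = 0.276) and with median centring (0.0634). No member of these 3 lists passed by either adjustment.

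Interferon response genes were shifted down through experiment 4. Of 14 members 11 were lower, with a median of -0.21 (camera adjusted p = 0.0101; adjusted p = 0.666 with an estimated correlation), and no member passed by either adjustment. The mean difference of the list was -0.0004, 0.06, -0.09 and -0.95 in experiments 1 to 4, and without experiment 4 the call was lost (adjusted p = 0.799). Gbp2 differed by -1.19 (SE 0.46) and Cxcl10 by -0.58 (SE 0.21), and without experiment 4 by -0.46 and -0.27.

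**Figure D2:**
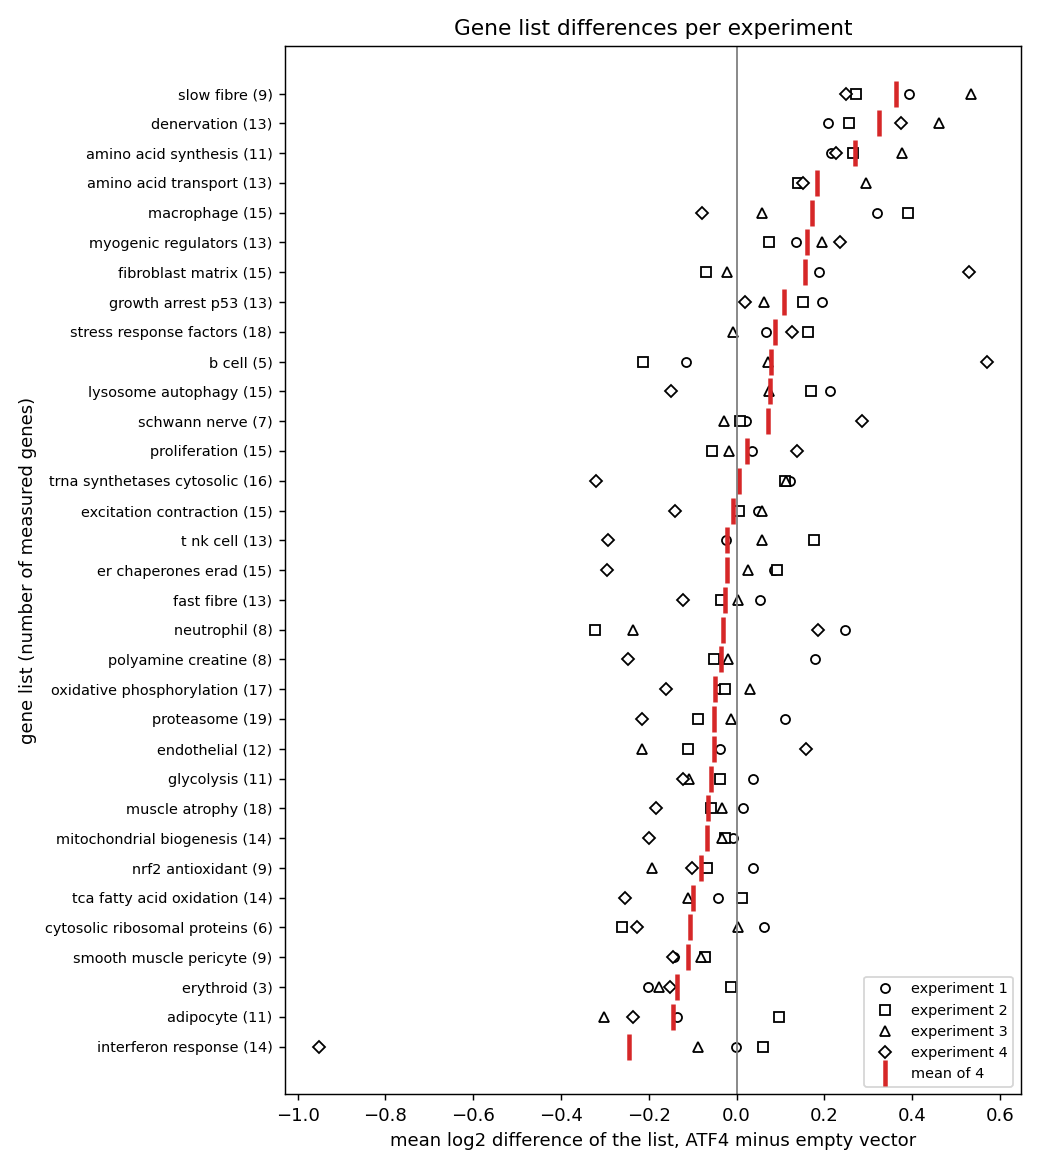
Mean log2 difference of each of the 33 gene lists (horizontal axis, ATF4 minus empty vector; measured members in parentheses), with 1 open symbol per experiment and a red bar at the mean of 4. Denervation, slow fibre, amino acid synthesis, amino acid transport, myogenic regulators and growth arrest lie above 0 in 4 of 4 experiments. Mitochondrial biogenesis, smooth muscle and pericyte, and erythroid lie below 0 in 4 of 4 experiments. The interferon list lies at -0.95 in experiment 4 and within 0.1 of 0 in the others.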

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

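In the tests below, those of chance splits and of the compressed range of an array were set out before their results were seen; the tests of swapped labels, of the muscle's own Atf4, of slow muscle tissue, of fibre RNA share, of the leg and of macrophage number were chosen after. Of 198 groups of 4 arrays, 9 had 1 array far from the other 3, where chance gives 10. With empty vector, Cdkn1a stood at 6.01 in experiment 3 against 5.17 to 5.29 in the others, Laptm5 at 7.91 against 6.50 to 6.66, Ctsz at 6.80 against 6.07 to 6.18 and the macrophage list mean at 6.73 against 5.85 to 5.90, also in experiment 3. Prdx1 stood at 7.63 and Rgs5 at 8.69 in experiment 4, and the smooth muscle and pericyte list mean at 5.65 in experiment 1. With ATF4, Sesn2 stood at 3.38 in experiment 3 against 3.87 to 3.92, and the neutrophil list mean at 3.90 in experiment 4 against 4.18 to 4.22.

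The 8 arrays have 35 splits into 4 and 4, fitted here without the pairing. Only the real split gave 3 probe sets, and the highest other split gave 1. Most of these splits do not part all 4 pairs, as the real one does, so they do not exclude chance. This comparison also does not cover the paired calls, since H19 is not among those 3 probe sets. The splits that part all 4 pairs, as the real one does, number 8, too few for a share under 0.05. The highest other of these gave 0 probe sets and 5 lists, and among the 27 that part fewer pairs the highest gave 1 and 10. For the lists in the same fit chance cannot be excluded, since 10 splits called as many as the real 8 lists and the highest other called 10. Exchanging the labels within pairs gives 8 arrangements, too few for a share under 0.05. In the paired fit 1 arrangement, the real one, gave 3 probe sets (highest other 0), 1 gave 9 lists (highest other 8), and 1 gave a denervation mean difference as far from 0 as the real 0.33 (highest other 0.22).

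The first pattern is the small Atf4 difference beside higher ATF4-linked genes. If ATF4 raises the amino acid synthesis list, swapped labels within a pair would lower it in that pair. It was higher in 4 of 4 pairs, which on that premise argues against a swap. The premise is part of the pattern itself, so this is no independent check of the labels. The muscle's own transcript may hide the plasmid's, since the probe set was at the 92.8 percentile of all probe sets with empty vector, and this stays open because the probe positions are not known here.

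The second pattern is the higher slow fibre and denervation lists. Slow muscle tissue in the samples would raise Myl2, which differed by -0.863, and by -0.35 without experiment 4. Myl2 stood at 7.57 with empty vector against 4.29 for Tnni1, a level that can hide a small share of slow tissue, so this stays open. A lower share of fibre RNA would lower the transcripts of fibres, which make up most of both lists. The mean differences were 0.362 (SD 0.13) for slow fibre and 0.326 (SD 0.11) for denervation genes, above 0 in 4 of 4 pairs. With quantile normalization they were 0.416 and 0.329. These rises are the pattern itself, so they are no separate test of the fibre share. They show only that a lower share alone would not produce the pattern. Ncam1 is expressed by other cells too. Such a share would also raise the markers of all other cells, and the smooth muscle and pericyte list without Des, a gene that fibres express too, and the red cell list were lower in 4 of 4 pairs (-0.12, SD 0.03, and -0.14, SD 0.08). Adipocyte (-0.14) and endothelial (-0.05) means were lower, and macrophage (0.17) and fibroblast and matrix means (0.16) were higher. The 10 lists of other cells were not shown to spread more than lists shuffled within pairs (permutation p = 0.314). These markers therefore do not decide the fibre share. A change in macrophages or fibroblasts themselves stays open. The leg cannot be told apart from the plasmid, since 0 arrays have ATF4 in the left leg, and an effect of ATF4 stays among the open explanations.

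The third pattern is the low interferon list in the ATF4-labelled array of experiment 4. A compressed signal range would vanish with quantile normalization, and the difference stayed at -0.839. Fewer macrophages would lower their markers as much, and these differed by -0.0784, against -0.95 for the interferon list. A first pair of tests, for more macrophages or lymphocytes in the empty vector muscle, was dropped because it assumed a high empty vector array, while the ATF4-labelled array was the one out of range. Biological variation between the muscles of that experiment was not tested.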

How the results depend on the processing

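The exact permutation of list means was chosen after the data were examined; the other settings were set before. Against 3 probe sets (2 genes), the counts of changed probe sets, genes and probe sets changed at least 1.5-fold were 13, 12 and 13 with a random replicate block (consensus correlation 0.27), 0, 0 and 0 without the variance trend or with median centring, 7, 6 and 7 without the dimmest 25% of probe sets, 12, 10 and 12 without the dimmest 50%, and 18, 16 and 18 with array weights. The array weights were equal within each pair and highest for experiment 3, so that setting weighted experiments. At an unadjusted p under 0.05 limma gave 985 probe sets without the trend and 929 with median centring. At a threshold of 0.01 there were 0 probe sets and 0 genes, at 0.10 there were 7 and 6, and against a 1.2-fold limit 0 and 0. Leaving out each experiment in turn gave 0 to 2 probe sets, 0 to 0 genes and 0 to 2 probe sets changed at least 1.5-fold. Without the pairing block there were 3 probe sets, 2 of them shared with the paired fit, and leaving out each array in turn gave 0 to 3. The robust prior, quantile normalization and the mean of a gene's probe sets kept each count within 1.5 times. Fewer probe sets tested is part of the dim filters' construction, and otherwise the cause was not tested. The adjusted p of H19 ranged from 0.003 to 0.211 and that of Tnni1 from 0.0043 to 0.292. Neither changed direction, and Atf4 did not pass under any setting in which it was fitted. The number of shifted lists, 9, became 0 with an estimated correlation, 0 with fry and 0 in the exact permutation of list means, and 6 to 11 without the pairing, without the dimmest 25%, with either scaling and without each experiment. The permutation cannot give a p under 0.0286, which was 0.236 after adjustment. Lists were not run with the random block, other priors, array weights or without the dimmest 50%. Denervation, slow fibre and amino acid synthesis were called without each experiment in turn. Of the lists that were not called, 11 changed the direction of the camera test under at least 1 alternative. Leaving the pairing out changed the calls of H19, Tnnt2 and the myogenic, macrophage and citric acid cycle lists, and the random block added 10 probe sets to the 3, among them Tnnt2, Uchl1, Ankrd1, Asns, Map1b, Igf2 and Slc7a5. Detection calls were not used here, so signal over background was not measured and dim probe sets are the least certain.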

Other observations

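The test of sarcomere strain genes was set out before its result was seen, and the tests of imprinted and developing muscle genes, in the form given here, were chosen after. Vessel-wall and immune markers outside the comparisons above went both ways. Smooth muscle and pericyte markers had a list mean lower in 4 of 4 pairs, with 5 of 9 members lower and a median of -0.04 that turned positive with quantile normalization (camera adjusted p = 0.199). Tagln, the smooth muscle protein transgelin, differed by -0.56 (SE 0.17) and Rgs5, a pericyte gene, by -0.45 (SE 0.16), or -0.25 without experiment 4, and neither passed. The exact permutation test of the list mean gave p = 0.0286 and 0.236 after adjustment over 33 lists. Endothelial markers had 9 of 12 lower and a median of -0.05 (camera adjusted p = 0.204; 0.0394 without experiment 4), with Tek at -0.33 (SE 0.12) and Ptprb at -0.28 (SE 0.11). Among T and NK cell markers Gzmb passed adjusted over the list alone and Gzma differed by -0.65 (SE 0.20), or -0.40 without experiment 4, while 9 of 13 members were higher with a median of 0.04, a mean of -0.02 and a camera test pointing down (adjusted p = 0.760); the median was close to 0 with median centring. Neutrophil markers had 7 of 8 higher, a median of 0.10 and a mean of -0.03 (camera adjusted p = 0.482), with S100a9 at -1.197 (SE 0.35). B cell markers (3 of 5 higher, median 0.12, adjusted p = 0.588) and red cell genes (3 of 3 lower, median -0.10, adjusted p = 0.204) were not shifted. The B cell median was -0.04 without experiment 4.

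The other metabolic and protein turnover lists were not shifted by camera. Oxidative phosphorylation had 12 of 17 members lower and a median of -0.05 (adjusted p = 0.199), mitochondrial biogenesis 11 of 14 lower and -0.06 (0.199), glycolysis 9 of 11 lower and -0.09 (0.205), the proteasome 14 of 19 lower and -0.05 (0.342), and cytosolic ribosomal proteins, of which 6 of 24 were measured, 4 lower and -0.15 (0.380). The oxidative phosphorylation and proteasome medians turned positive with quantile normalization. Without experiment 4 the proteasome and ribosomal protein medians were both 0.03. The ribosomal protein median was -0.02 without experiment 2. Polyamine and creatine genes had 5 of 8 lower and a median of -0.09 (0.588), with Gamt, of creatine synthesis, at 0.44 (SE 0.15; 0.27 without experiment 3) and the spermine oxidase gene Smox at -0.37 (SE 0.14; -0.22 without experiment 4). Lysosome and autophagy genes had 9 of 15 higher and a median of 0.02 that turned negative with median centring (0.205). That list was called with quantile normalization (adjusted p = 0.00884) and without experiment 4 (0.000769), and Ctsz, a lysosomal protease, differed by 0.33 (SE 0.11). Probe set 6969997, annotated to 2 genes, differed by -1.09 (SE 0.15, adjusted p = 0.131).

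H19 and Igf2, neighbouring imprinted genes, were both higher, and a candidate explanation is a shift of imprinted genes as a group. In a list of other imprinted genes, 9 of 13 were higher with a median of 0.08 (camera adjusted p = 0.211 over 3 lists). Dlk1, a member that the fixed myogenic list also holds, was left out after a first test with it. Genes of the strained sarcomere, tested because Ankrd1 and Csrp3 were higher, had 10 of 14 higher and a median of 0.06 (adjusted p = 0.0809). By the bounds set beforehand, an adjusted p of 0.05 or more, the strain value and the first imprinted value would have counted against these hypotheses, and were first recorded so. That reading was changed after the values were seen, because neither hypothesis forbids such a p while the median lies above 0. Neither hypothesis gained a call, and both stay open. Genes of developing muscle, tested because Tnnt2 and Tnni1 were higher, were tested without 3 members already seen, Myod1, Nes and Mybph. Of the others 9 of 11 were higher with a median of 0.16 (adjusted p = 0.0176). The adjusted p was 0.209 with an estimated correlation, and the exact permutation test gave p = 0.114. A shift of developmental genes may underlie this, and its call was lost with an estimated correlation.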
